A study of Mus musculus with 4 samples.

How the data were processed

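RNA from the fat pad beside the epididymis of male mice was measured on Clariom S Mouse arrays, a 1-colour Affymetrix design with a probe set for each annotated transcript cluster. The 4 arrays form a 2 by 2 layout with 1 array per group. The mice received either DMSO as vehicle or GW4869, a drug that blocks the release of extracellular vesicles, and they had either sham surgery or synergist ablation, which overloads a muscle by removing the muscles that work with it. The groups came from the sample titles, and the layout text of the series spells out their abbreviations. Whether an array holds RNA of 1 mouse or a pool is not given in the sources used here.

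The authors deposited log2 expression values per probe set, made with Partek and RMA per the submitters' processing notes. Versions, the RMA background step and the normalization settings are not given in the sources used here. The deposited log2 values run up to 19.93, higher than the raw brightness of an ordinary array scanner allows, and the step that gave them was not identified. A difference of 1 log2 unit is therefore a doubling on the deposited scale only. The same 4 genes stood at or above 19.5 on all 4 arrays.

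The table has 28846 rows, of which 22142 are transcript clusters, 64 unmapped transcripts and the rest array controls. A platform annotation gave 19572 probe sets 1 gene symbol, 45 of them outside the transcript clusters, and 0 probe sets several, and 2615 transcript clusters stayed unnamed. All 19572 Entrez identifiers were found in the RefSeq gene table, which altered 0 symbols. For each of 19505 genes the probe set with the highest mean over the arrays was kept. This choice mattered for 55 genes with several probe sets, and 0 of them had probe sets moving in opposite directions by 1.5-fold for overload under vehicle. Adrb3 is not analysed here, because the annotation names it for none of the probe sets used. No genome coordinates are given, because the build behind the probe sets is not given in the sources used here.

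The table carries no detection flags. A floor was set at the 40th percentile of gene means, log2 4.67, and 11703 genes lay above it. The median over negative control rows was between 4.77 and 5.20 on the 4 arrays, and the median over antigenomic background probes between 5.12 and 5.28. Their 95th percentiles reached 9.27 and 6.40, so values well above the floor can still lie within background, and a difference from such a reading is a bound at best. For a named gene with an array under the floor, either levels are given or the floor is taken for that array, which makes the difference a bound on its size. List medians and counts use the values as deposited unless said otherwise. The floor is on the mean over arrays, so a gene high on 1 array alone can pass it.

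With 1 array per group there is no replicate error, and the number of arrays limits the precision of every value. No p-value or count of significant genes was computed. Differences of log2 values were taken for overload under vehicle, overload under GW4869, GW4869 in sham mice, GW4869 in overloaded mice, and the difference between the overload differences. Overload under vehicle and GW4869 in sham both subtract the vehicle sham array, so its readings enter both. Genes at least 1.5-fold apart were counted. A count of this kind describes 2 arrays, not 2 conditions.

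Gene lists for 41 pathways and cell types, with 734 members of which 663 were measured, were fixed before the data were examined, as were the comparisons, the rule for naming genes and most of the alternative settings. A list was summarised by the median difference of its members above the floor. Its percentile among 10000 random lists of the same size, matched on mean expression in 20 bins, describes where it lies on these arrays. A list stands apart where this percentile lies outside the central 95%, between 2.5 and 97.5. Lists with fewer than 5 members above the floor got no percentile. For 35 independent lists, 1.75 would stand apart by chance in a comparison. Lists share genes and genes move together, so this number is a guide only.

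The genes named are the 12 highest and 12 lowest differences for each overload comparison, the 8 highest and 8 lowest for the difference between them, the 6 highest and 6 lowest for each GW4869 comparison, Tfap2a, and up to 4 members with the largest differences in each list described. Predicted gene models and olfactory, vomeronasal and taste receptors were left out. Major urinary protein genes are given as a family, since their probe sets can cross-hybridise. Smaller lists of testis, epididymis, seminal vesicle and clock genes were added after seeing the data, and any other gene outside the rule is marked where it is named.

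The counting and list steps were tested on simulated data built for overload under vehicle with 11703 genes and noise of SD 0.3. Of 200 genes moved by 1 log2 unit, 82.0% passed the 1.5-fold threshold, and of 200 moved by 2 log2 units, 100.0% did. Among unmoved genes 16.8% and 16.2% passed it too. Of 35 lists moved by 0.5 log2 units, 32 stood apart, and 0 of 35 unmoved lists did. The simulated noise was independent between genes, and the real differences for this comparison spread more widely, with an SD of 1.61. These rates therefore show that the steps work and do not carry over to the real arrays.

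Alternatives fixed in advance were centring each array on the median of all genes, quantile normalization, removal of an intensity trend by lowess (span 0.3, 3 robustness iterations), no floor, a floor at the 60th percentile, the mean over probe sets, a 2-fold threshold, the mean over list members, and unmatched random lists. Added after seeing the data were setting values under the floor to the floor, centring on genes above the floor, centring on mature adipocyte genes, removal of epididymal and sperm genes, removal of genes spanning 4 log2 units or more from the correlation, and a comparison of the vehicle overload array with the GW4869 sham array. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.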

Results

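Expression in epididymal fat was profiled on 4 arrays, 1 for each combination of injection (vehicle or GW4869) and surgery (sham or muscle overload). The series title concerns vesicles shed by overloaded muscle and the breakdown of fat, and GW4869 blocks vesicle release. Overload against sham under vehicle therefore asks how fat differs after overload, and the same contrast under GW4869 asks whether that difference needs vesicle release. No difference has a replicate check, so all values describe these 4 arrays and carry no error.

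The arrays differed most in transcripts of the male reproductive tract. Genes of mature adipocytes were high on every array, with list medians of log2 16.64 (vehicle sham), 16.90 (vehicle overload), 16.82 (GW4869 sham) and 16.38 (GW4869 overload). The list of sperm and testis genes had a median of 14.04 on the vehicle sham array against 3.70, 3.17 and 4.34 on the vehicle overload, GW4869 sham and GW4869 overload arrays. All 15 of its measured members stood at least 4 log2 units above the vehicle overload array there. Among them were Prm1 and Prm2, which package sperm DNA, at 17.40 and 17.92. The list of epididymal epithelium genes had a median of 12.47 on the GW4869 overload array, where 14 of 20 members stood that far above vehicle overload, and 4.50, 3.33 and 3.42 on vehicle sham, vehicle overload and GW4869 sham. On the vehicle sham array 6 of the 20 did, and on the GW4869 sham array 0. Gpx5, a glutathione peroxidase of the epididymis, was at 19.53 on the GW4869 overload array and at or below 4.51 on the others. Serpina1f, Ptgs2 and Pcp4, part of a set of 6 distal epididymis and vas deferens genes assembled after the values were seen, were high on both sham arrays. The median of that set was 13.15 in vehicle sham, 12.87 in GW4869 sham, 3.19 in vehicle overload and 5.33 in GW4869 overload.

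**Figure D1:**
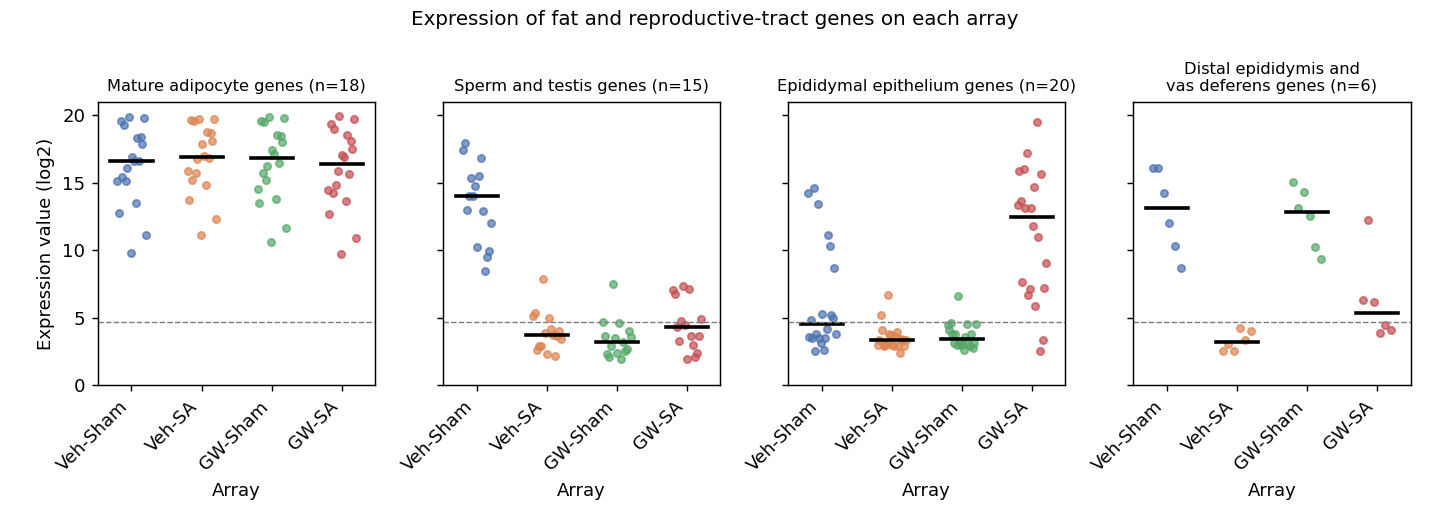
Each point is the log2 expression value of 1 gene on 1 array, for 18 mature adipocyte genes, 15 sperm and testis genes, 20 epididymal epithelium genes and 6 distal epididymis and vas deferens genes, with the list median as a bar and the expression floor of 4.67 as a dashed line. Adipocyte medians lie between 16.38 and 16.90, while the sperm list stands at 14.04 on the vehicle sham array and the epididymal list at 12.47 on the GW4869 overload array.

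Genes that stood at least 4 log2 units above all the other arrays numbered 335 for vehicle sham, 47 for GW4869 overload, 0 for vehicle overload and 0 for GW4869 sham. Across the 11703 genes above the floor, the vehicle sham array correlated with the others at r = 0.84 (vehicle overload), 0.85 (GW4869 sham) and 0.83 (GW4869 overload). Vehicle overload and GW4869 sham correlated at 0.97, although they share neither injection nor surgery. These are correlations across genes, which are not independent replicates.

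Overload under vehicle came with higher medians of the fatty acid oxidation, glucose handling, triglyceride synthesis and clock lists, at 0.84, 0.67, 0.61 and 0.82, or 0.58, 0.41, 0.34 and 0.56 when arrays were centred on adipocyte genes. Acsm3, a medium-chain acyl-CoA synthetase of mitochondria, was 2.95 log2 units higher in overload. Irs1, an insulin receptor substrate, was 2.68 higher, and Hcar2, the receptor through which ketone bodies and niacin restrain lipolysis, was 2.39 higher. The largest negative differences belonged to the reproductive tract. Ldhc, Prm2, Odf1 and Prm1 of sperm had levels of 15.35 to 17.92 in vehicle sham and 2.94 to 5.33 in overload, and Serpina1f, Spink8, Defb38 and Adam7 of the epididymis had 14.64 to 16.55 and 2.52 to 3.82. Ptgs2, the inducible cyclooxygenase, stood at 14.26 in sham and 2.52 in overload, and Meig1, Fabp9 and Pabpc2, which act in the testis, were at 15.17, 15.40 and 13.76 in sham and under the floor in overload.

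The fatty acid oxidation list had a median log2 difference of 0.84, with 11 of 19 members at least 1.5-fold higher, 1 lower and 7 between. Ehhadh, a peroxisomal enzyme of this route, and Slc25a20, the carnitine carrier, were both 1.45 higher, and Acadl was 1.16 higher. Cpt1b, which is also expressed in muscle and testis, had -3.01 or lower. Insulin and glucose handling genes had a median of 0.67 with 12 of 22 higher and 1 lower. Pik3r1 (1.55) and Tbc1d4 (1.41), which relay the insulin signal, were among the higher ones, and Hk1, a hexokinase with a sperm form, had -4.50. Triglyceride synthesis genes had a median of 0.61 with 7 of 13 higher and 2 lower, led by Dgat1 (2.18) and Gpam (1.83), the last and the entry enzyme of the route. Fatty acid synthesis genes had a median of 0.04, or -0.06 after trend removal and -0.23 when centred on adipocyte genes, with Acacb at 1.87 and the desaturase Fads2 at -4.98. Thermogenic genes had a median of 0.88 over 6 of 14 measured members, with Ppargc1a (1.92) and Ebf2 (1.49) higher. Ucp1, Cidea, Dio2, Prdm16 and Elovl3 lay under the floor, Cox8b and Cox7a1 near it, and the median was 0.47 with values under the floor set to it and 0.08 over all 14, both within the random range. Mature adipocyte genes had a median of 0.38, within the random range, with 8 of 18 higher and 0 lower (Slc2a4 1.38, Acvr1c 1.35).

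Clock genes had a median of 0.82 with 9 of 14 higher and 1 lower. Dbp, Per2, Per3 and Nr1d2 peak together in the daily cycle. Dbp, Per3 and Nr1d2 were 1.99, 1.71 and 1.62 higher, and Per2 stood at 7.38 in overload against a sham reading within background. Endothelial markers had a median of 0.78 (8 of 15 higher, 0 lower; Vwf 1.57, Emcn 1.15), and macrophage markers 0.65 (11 of 19 higher, 0 lower; Fcgr1 2.17, Gpnmb 1.85). Centred on adipocyte genes these were 0.52 and 0.39. Neutrophil markers had 1.05 over 5 members, or 0.47, within the random range, with values under the floor set to it (Retnlg 0.65, S100a8 0.47) and 0.11 over all 10 measured members. Heat shock genes had a median of -0.56 (-0.09 with all-gene centring) and genes of the unfolded protein response -0.44, the latter turning to 0.03 when arrays were centred on all genes. Hspa4l (-4.01), a chaperone abundant in testis, and Dnajb1 (-1.98) led the first, and Sdf2l1 (-1.58) and Hspa5 (-1.36) the second. Vehicle sham carried testis transcripts, so their part in both medians cannot be told apart. Cholesterol synthesis genes had a median of -0.24, with Sqle at -2.34 or lower and Fdps at -1.72, and 0.24 with all-gene centring. Smooth muscle markers had a median of -1.12, with 9 of 13 lower, Actg2 at -9.99 or lower and Cnn1 at -8.68. Over all 14 measured they stood at 10.41 in sham and 7.91 in overload, the direction of the distal tract set. A part from tract tissue cannot be told apart. Sperm and testis genes had a median of -10.74 in the same comparison, with 12 of 12 lower. Epididymal genes had -0.59, or 0.00 with values under the floor set to it, with 8 of 16 lower. Mesothelial markers had -0.18, with the keratins Krt18 and Krt8 at -3.04 and -2.10, and turned to 0.29 with all-gene centring.

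In total 3537 genes were at least 1.5-fold higher in overload and 1972 lower, and the median gene differed by 0.26. The other genes of the largest positive differences were Tnfrsf14 (2.43) and Cyp2f2 (2.41), with Mmp7 and Pon1 at 9.16 and 7.10 in overload against sham readings within background, and Rassf6, Vnn1, Zim1, Mib2 and Tfap4 stood at 6.33, 7.41, 6.92, 6.80 and 6.65 in overload and under the floor in sham. Differences of at least 4 log2 units were positive for 1 gene and negative for 445. Of 35 lists, 15 stood apart from random lists, 8 above and 7 below. The share of higher genes was 64.2%, but 83.6% with all-gene centring, 39.2% after trend removal and 42.9% when centred on adipocyte genes, so the direction of the bulk of genes depends on the scaling. Removing the epididymal and sperm list genes left 3536 higher and 1952 lower. That step kept 11675 of 11703 genes, and most of the 445 strongly lower genes stayed in. It could therefore hardly move the counts and does not decide how much of them comes from tract RNA.

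Overload under GW4869 came with a lower median of the fatty acid synthesis list and higher medians of the inflammatory, heat shock and epididymal lists. Fasn, the fatty acid synthase, had a log2 difference of -3.64, from 16.22 in sham to 12.58 in overload. Il1b, a macrophage cytokine, was at 9.88 against 4.88, and Hspa1b and Hspa1a, inducible chaperones, were 3.76 and 3.63 higher. The largest positive differences were epididymal. Gpx5, Spag11b, Adam7, Ovch2, Defb20 and Lcn8 stood between 14.70 and 19.53 in overload and at 4.51 or less in sham, and Lypd8, Fgg, Muc15, Cstdc2 and Cst11 between 13.15 and 15.82 against sham values under the floor. Slc38a5, an amino acid transporter, was at 17.47 against 5.79.

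The fatty acid synthesis list had a median of -1.38, below all 10000 random lists, with 10 of 15 members lower and 2 higher. After Fasn the lowest were Pnpla3 (-2.66), Acss2 (-2.13) and Me1 (-1.99), which supplies NADPH for lipid synthesis. Triglyceride synthesis genes had a median of -0.40, within the random range and 0.04 when centred on adipocyte genes, with Dgat2 (-2.09), Mogat1 (-1.74) and Agpat2 (-1.59) the lowest. Fatty acid uptake genes had -0.46 (4 of 11 lower, 1 higher; Lmf1 -1.04, Cav1 -0.95), fatty acid oxidation genes -0.40 (6 of 19 lower, 0 higher; Acads -0.73, Cpt2 -0.71), insulin and glucose genes -0.40 (8 of 22 lower, 1 higher; Irs3 -1.56, Pik3r1 -1.54) and thermogenic genes -0.61 (3 of 6 lower, 1 higher; Cox8b -0.66 or lower). Centring on adipocyte genes adds the same amount to every difference here, which took the median gene from -0.04 to 0.40 and the oxidation and glucose medians to 0.04. Synthesis genes then had -0.94, thermogenic genes -0.17 and uptake genes -0.02. Mature adipocyte genes themselves had a median of -0.40, at percentile 3.14, with 5 of 18 lower and 0 higher, among them Lep (-1.47), the gene for leptin, and Slc2a4 (-0.89).

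Inflammatory and acute phase genes had a median of 2.28, with 7 of 10 higher and 1 lower. Lcn2, made by inflamed tissue and by epididymis, was 5.51 higher, while Ptgs2 had -8.12. Neutrophil markers had a median of 2.88 over 5 members and 0.66 over all 10 measured, with Csf3r 2.88 higher and S100a8 and S100a9 at 8.63 and 7.94 against readings within background. Heat shock genes had a median of 1.25 (7 of 12 higher, 2 lower) and unfolded protein response genes 0.49 (6 of 15 higher, 0 lower; Hspa5 1.43, Atf4 1.39, Ddit3 1.37). Over all measured members, both lists were highest on GW4869 overload (10.73 and 13.45) and next on vehicle sham (10.07 and 13.11). They had 9.46 and 12.62 on vehicle overload, and 9.68 and 13.01 on GW4869 sham. For both lists a part from tract tissue cannot be told apart. Interferon-induced genes had 0.48, with Cxcl10 3.08 higher, a bound at best because its sham reading lay within background. Ribosomal protein genes had 0.47, with Rplp0 1.05 higher. Endothelial markers had a median of -0.57 (7 of 15 lower, 0 higher; Vwf -1.37, Erg -1.22), fibroblast and progenitor markers -0.80 (8 of 14 lower, 0 higher; Mfap5 -1.78, Cd248 -1.51) and matrix genes -0.49 (8 of 22 lower, 2 higher), although Timp1, an inhibitor of matrix proteases, was 3.66 higher. Centred on adipocyte genes these 3 medians were -0.13, -0.36 and -0.05. Clock genes had 0.15, within the random range, with 5 of 14 higher and 2 lower (Bhlhe41 2.99, Dbp 2.27, Arntl -1.58). Mast cell markers had -1.51 over 7 members and -0.51 over all 10 measured, with Tpsb2 at -1.93 and Kit, which epithelial cells can also express, 2.75 higher. Mesothelial markers had -1.03, yet the epithelial keratins Krt8 and Krt18 were 3.99 and 3.58 higher. Smooth muscle markers had -1.58 (Cnn1 -5.15, Myh11 -3.42). Over all 14 measured they stood at 10.87 in sham and 8.79 in overload, the direction of the distal tract set. A part from tract tissue cannot be told apart. Skeletal muscle markers had -0.96 over 7 members (Casq1 -1.59 or lower), but -0.19, within the random range, over all 20 measured. In the same comparison the epididymal list had a median of 9.21 with 15 of 16 members higher, and the sperm list 1.52, or 0.00 with values under the floor set to it.

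**Figure D2:**
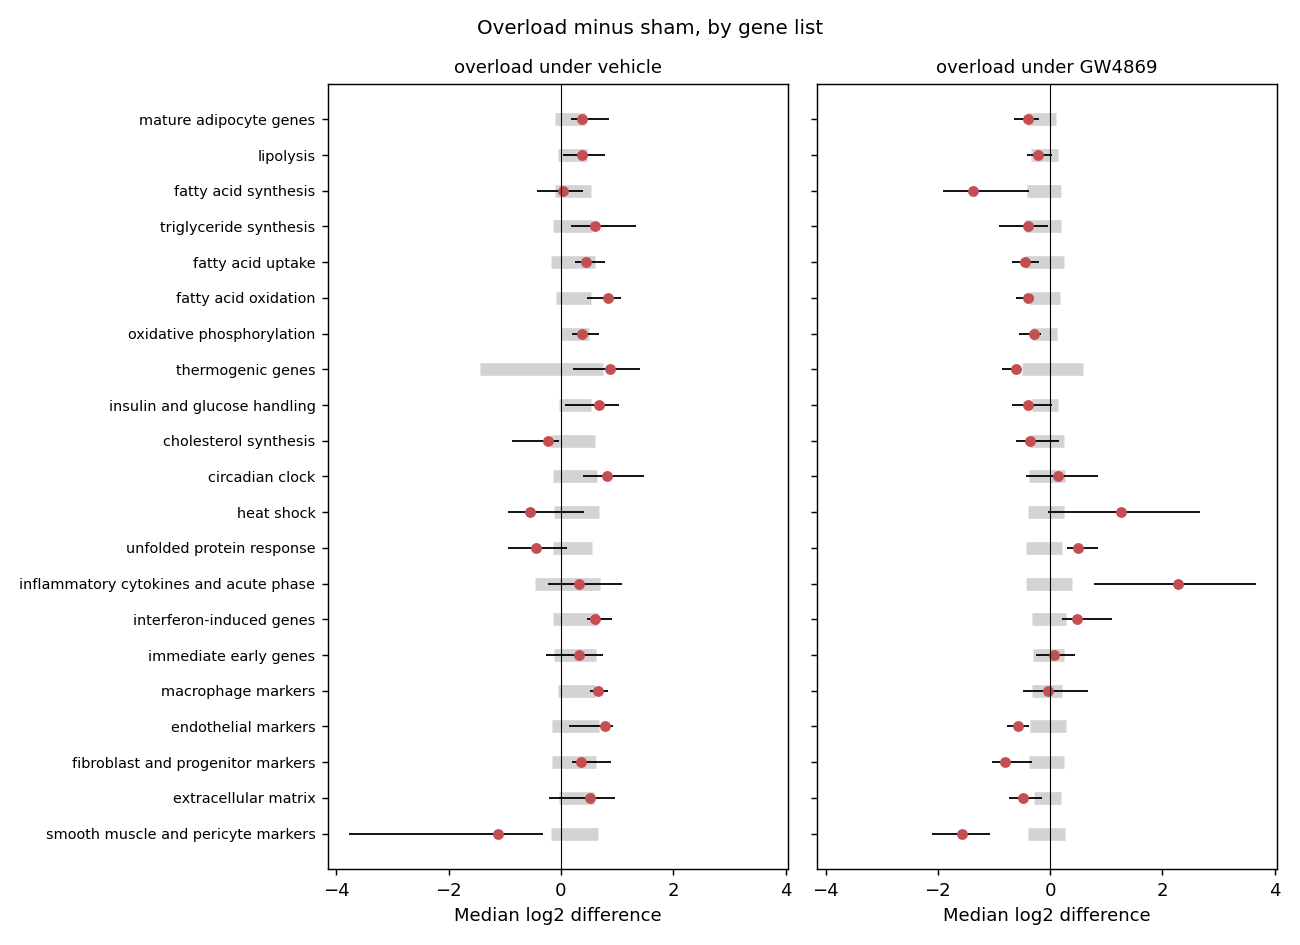
Red points are median log2 differences, overload minus sham, of 21 gene lists under vehicle and under GW4869, with black lines for the interquartile range of members and grey bars for the central 95% of 10000 random lists matched on expression. Fatty acid oxidation genes lie at 0.84 under vehicle and -0.40 under GW4869 (0.04 when centred on adipocyte genes), and fatty acid synthesis genes at 0.04 (-0.06 after trend removal) and -1.38.

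In total 1564 genes were at least 1.5-fold higher and 1787 lower, with a median gene difference of -0.04. The largest negative differences were in Serpina1f, Pcp4, Ptgs2, Cited1, Defb43, Anxa13, Fxyd4, Cnn1, Abcg2, Kcnj16, Kif5c and P2rx1. They stood at 8.40 to 15.31 in sham and 2.94 to 10.17 in overload, and each of the 12 was also lower in overload under vehicle. Serpina1f, Pcp4, Ptgs2, Cited1 and Fxyd4 belong to the distal epididymis and vas deferens set. That set had medians of 13.15 and 12.87 on the vehicle and GW4869 sham arrays, and 3.19 and 5.33 in overload. It was assembled after the values were seen and shares these genes with the ranking, so its medians are no separate evidence. Of the lists fixed beforehand, 0 of 20 epididymal and 0 of 15 sperm genes on GW4869 sham stood at least 4 log2 units above vehicle overload. The shared direction still cannot be told apart from distal tract RNA on both sham arrays. Of 35 lists 21 stood apart, 9 above and 12 below. The share of higher genes was 46.7%, against 34.9% with all-gene centring and 87.7% when centred on adipocyte genes. Without the epididymal and sperm list genes 1540 were higher and 1787 lower. Here too 11675 of 11703 genes were kept, so the step could hardly move the counts and does not decide on a part from tract RNA.

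Lipolysis genes, the group named in the series title, had medians within the random range in both overload comparisons, although their mean under vehicle (0.40) lay above it at percentile 97.6. Under vehicle their median was 0.38 (percentile 92.0), with 10 of 24 members at least 1.5-fold higher and 1 lower. Adcy4 (1.57) and Adcy3 (1.17), which make cAMP, and G0s2 (1.31), which inhibits adipose triglyceride lipase, were higher, and Prkg1 had -1.63. Under GW4869 the median was -0.21 (percentile 18.2), or 0.22 when centred on adipocyte genes, with 1 of 24 higher and 2 lower. Ptger3, a receptor that restrains lipolysis, had -1.84, Adcy5 -0.70, and Prkacb and Adcy4 were 0.76 and 0.56 higher. The lipase genes Pnpla2 and Lipe, chosen after their values were seen, were 0.42 and 0.91 higher in overload under vehicle and had 0.01 and -0.37 under GW4869. Mature adipocyte genes had medians of 0.38 and -0.40 in these comparisons. The 0.38 equals the lipolysis median because both lists hold Cidec and Pnpla2, their middle genes there.

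Tfap2a, an AP-2 transcription factor chosen from background knowledge before the data were examined, had log2 values of 5.33 in vehicle sham, 4.28 in vehicle overload, 5.91 in GW4869 sham and 6.96 in GW4869 overload. The vehicle overload value lies under the floor, and the values of both sham arrays also lie below the 95th percentile of antigenomic background probes, 6.34 to 6.40. With values under the floor set to it, the vehicle difference is -0.67. The difference under vehicle is thus between 2 readings at background level. The overload differences were -1.05 under vehicle and 1.05 under GW4869, and centring on all genes moved the first to -0.58. Tfap2b had 7.42, 2.67, 5.17 and 4.89, and Tfap2c was under the floor on every array. The tract lists were high on the same arrays that had the highest values of Tfap2b (vehicle sham) and Tfap2a (GW4869 overload). Reported targets of miR-1, a muscle microRNA, had medians of 0.37 and -0.03 in the overload comparisons, both within the random range, and the second was 0.03 after trend removal. Met and Sfrp1 were each 1.43 higher under vehicle, and Gja1 was 2.83 higher under GW4869. Genes induced by cAMP had medians of 0.48, within the random range, and 0.61, above it, the latter 0.24 and within it over all 10 measured members, with Ppargc1a 1.92 and 0.84 higher. Genes of vesicle biogenesis had 0.18 (-0.10 after trend removal) and 0.04 (-0.06 with all-gene centring), with Rab27b at 1.06 or more and -1.09 or lower. Genes of sphingolipid metabolism, among them targets of GW4869, had 0.36 (-0.01 after trend removal) and -0.28 (0.16 when centred on adipocyte genes), with Smpd3 at 0.38 and -1.28.

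**Figure D3:**
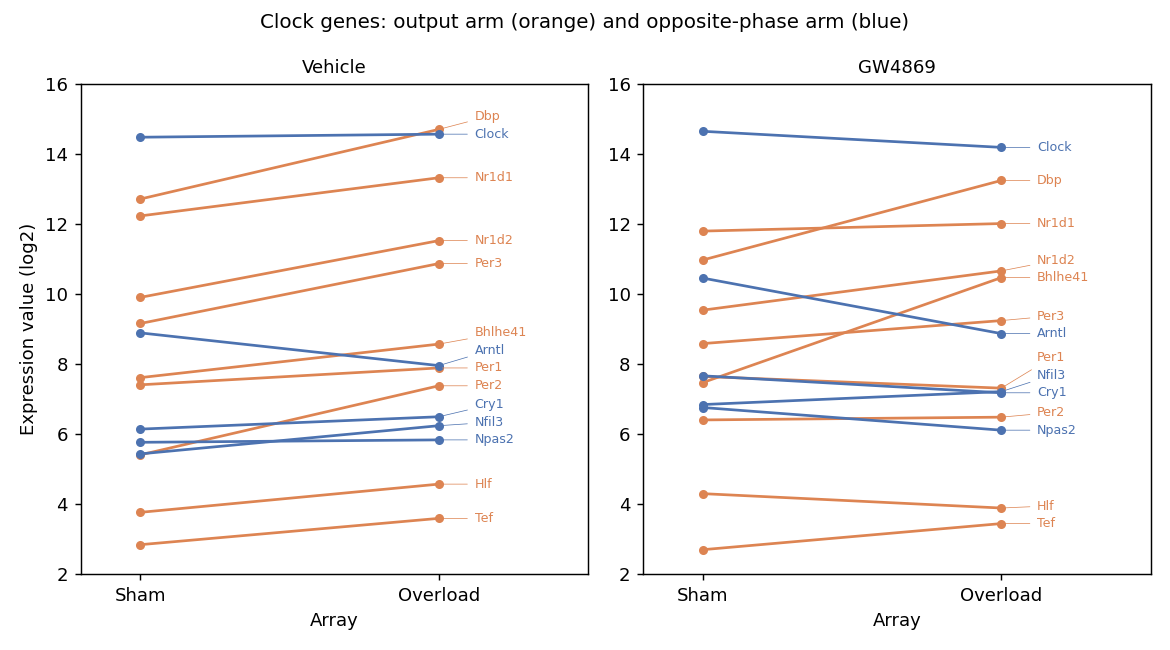
Lines join the log2 values of clock genes on the sham and overload arrays under vehicle and under GW4869, with 9 genes of the output arm in orange and 5 genes of an opposite-phase arm in blue, arms assembled after the values were seen. Dbp is 1.99 higher in overload under vehicle and 2.27 under GW4869, while Per1 has 0.48 and -0.33 and Arntl -0.93 and -1.58.

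GW4869 in sham mice came with higher medians of the macrophage, inflammatory, matrix and glucocorticoid-induced lists. Cxcl13, a B cell chemokine, was 6.10 log2 units higher and Gpnmb, a marker of lipid-laden macrophages, 5.42. All 19 macrophage markers above the floor were at least 1.5-fold higher, with a median of 1.69 (Mpeg1 2.99, Ctss 2.30, Itgam 2.26). Atp6v0d2 (3.94) and Wfdc17 (3.73) were higher as well, Nr4a3 stood at 9.65 against a reading within background, and Chil1 stood at 8.12 against a value under the floor. The lowest differences were the sperm and epididymal genes Ldhc, Prm2, Defb38, Prm1, Odf1 and Fabp9, at 15.35 to 17.92 in vehicle sham and 1.97 to 4.71 under GW4869, and the sperm list median was -11.08.

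Inflammatory genes had a median of 2.21 (7 of 10 higher, 0 lower; Saa3 2.34, Ccl7 2.24), or 1.23 with values under the floor set to it and 0.73 over all 20 measured members. Medians were 1.11 for interferon-induced genes (11 of 16 higher, 0 lower; Oasl2 2.94, Irf7 2.18) and 0.85 for immediate early genes (13 of 20 higher, 0 lower; Myc 3.15, Ier3 2.77). Neutrophil markers had 1.42, or 0.83, within the random range, with values under the floor set to it and 0.53 over all 10 measured members. Glucocorticoid-induced genes had a median of 1.15 with 10 of 14 higher and 0 lower, led by Pdk4 (2.32), Errfi1 (1.98) and Fkbp5 (1.53). Matrix genes had 1.06 (15 of 22 higher, 0 lower; Mmp2 1.94, Mmp14 1.89), fibroblast markers 0.69 (Lum 2.02), mesothelial markers 0.76 (Wt1 2.03) and miR-1 targets 0.76 (10 of 16 higher, 0 lower; Sfrp1 1.51). After trend removal the immediate early, fibroblast, mesothelial and miR-1 target medians were 0.49, 0.39, 0.50 and 0.48. Cholesterol synthesis genes had -0.26 (Fdft1 -1.78), cell cycle genes -0.29 (Ccnb2 -4.33) and unfolded protein response genes -0.12 (Creld2 -0.95). With all-gene centring these were 0.11, 0.07 and 0.25. Over all 24 measured members, cell cycle genes were highest on vehicle sham, at 6.23. They had 5.06, 5.15 and 5.45 on vehicle overload, GW4869 sham and GW4869 overload. Vehicle sham carried testis transcripts, so their part in this difference cannot be told apart. Oxidative phosphorylation genes had 0.03, just below the random range, and -0.15 after trend removal. Lipolysis genes had 0.10 (-0.06 after trend removal; Prkg1 -1.20, Adcy3 0.97), mature adipocyte genes 0.17 and fatty acid synthesis genes 0.36, all within the random range. In total 3385 genes were higher and 1690 lower, 16 of 35 lists stood apart, and the median gene differed by 0.27. The share of higher genes was 66.7%, against 83.4% with all-gene centring, 40.5% after trend removal and 52.1% when centred on adipocyte genes.

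**Figure D4:**
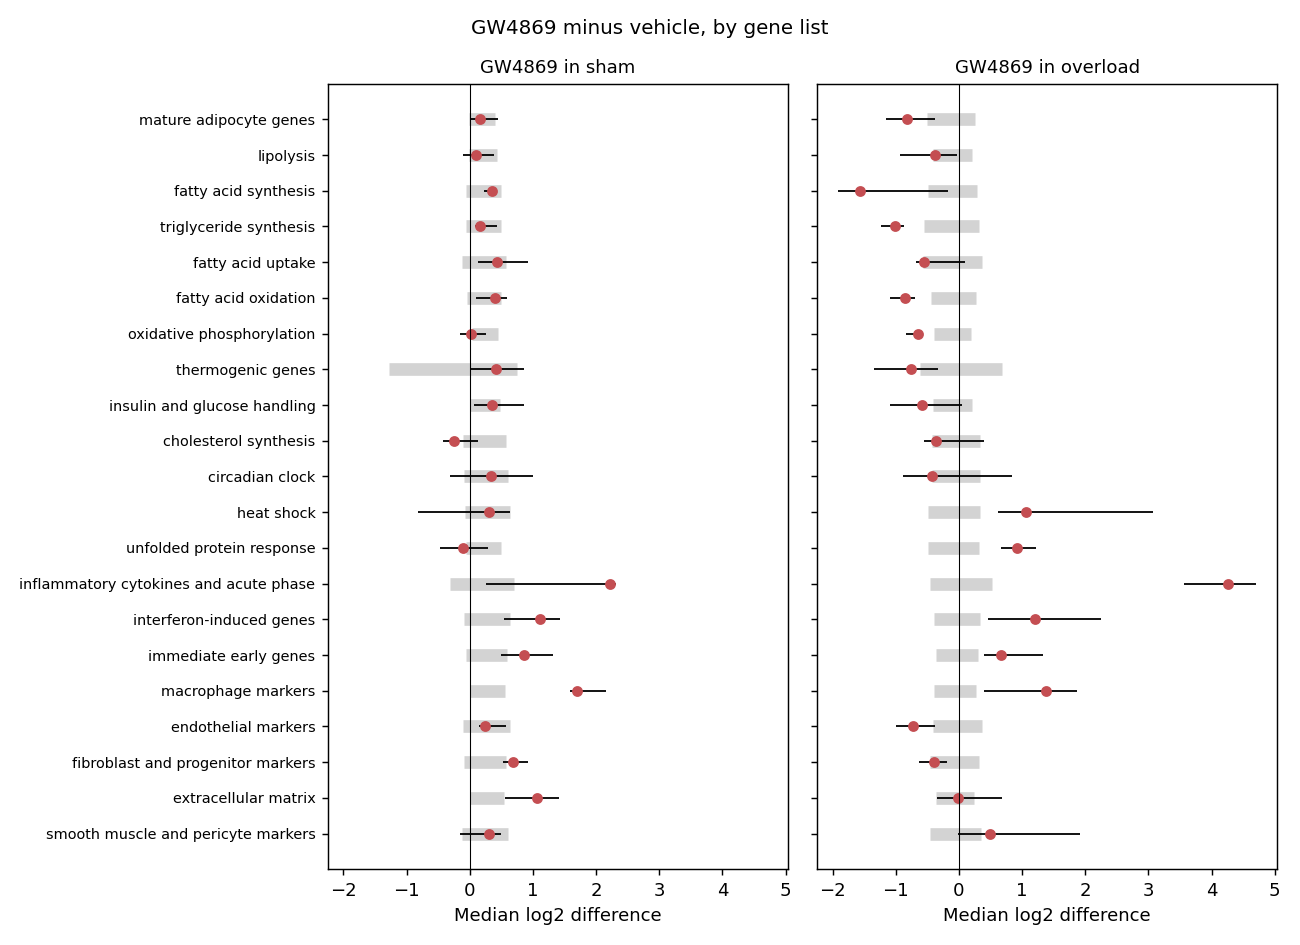
Red points are median log2 differences, GW4869 minus vehicle, of 21 gene lists in sham and in overloaded mice, with black lines for the interquartile range of members and grey bars for the central 95% of 10000 matched random lists. Macrophage markers lie at 1.69 and 1.38, and inflammatory genes at 2.21 and 4.27.

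GW4869 in overloaded mice came with a higher median of the inflammatory list and lower medians of the fatty acid synthesis, triglyceride synthesis, fatty acid oxidation and oxidative phosphorylation lists. The inflammatory median was 4.27 over 10 members above the floor, 3.81 with values under the floor set to it and 3.25 over all 20 measured members. Lcn2 was 6.54 higher, Ccl3 at least 4.98 and Ccl2 4.60. Il1b was 4.75 higher, which is a bound at best because its vehicle reading lay within background. Macrophage markers had a median of 1.38 (13 of 19 higher, 0 lower; Gpnmb 5.02, Adgre1 2.56), neutrophil markers 2.87 (0.85 over all 10 measured; S100a9 at least 3.27) and interferon-induced genes 1.20 (Cxcl10 at least 3.23, Ifit1 2.84). Fasn had -3.07, and the fatty acid synthesis list a median of -1.57 with 9 of 15 lower and 2 higher. The higher ones were Fads2 (5.25) and Elovl6 (2.80). The largest positive differences were the epididymal genes Gpx5, Spag11b, Adam7, Lypd8, Lcn8 and Defb20, between 15.63 and 19.53 against values under the floor, and the epididymal median was 9.79, or 8.50 with values under the floor set to it.

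Oxidation genes had a median of -0.85 (16 of 19 lower, 0 higher; Cpt2 -1.52, Ehhadh -1.38), oxidative phosphorylation genes -0.65 (19 of 27 lower, 0 higher; Ndufa9 -1.47, Sdha -1.09), triglyceride synthesis genes -1.02 (12 of 13 lower, 0 higher; Mogat1 -2.34), fatty acid uptake genes -0.55, within the random range (4 of 11 lower, 1 higher), and mature adipocyte genes -0.83 (11 of 18 lower, 0 higher; Pparg -1.41, Slc2a4 -1.41). Lipolysis genes had -0.39 (percentile 3.26), with 10 of 24 lower and 1 higher, and 0.14 when centred on adipocyte genes. Ptger3 (-2.01) and G0s2 (-1.77) were the lowest. Glucose handling genes had -0.58 (Irs1 -1.96), endothelial markers -0.72 (Vwf -1.54), mast cell markers -0.74 (-0.49 over all 10 measured; Mcpt4 -1.68) and thermogenic genes -0.76 (-0.34, within the random range, over all 14 measured; Cox8b -0.85 or lower). Angptl8, Rgs7bp, Pon1, Tecpr1 and Pnpla3 were at 4.27, 6.52, 4.49, 4.31 and 10.86 under GW4869 and at 6.82, 9.26, 7.10, 6.88 and 13.33 under vehicle. Heat shock genes had a median of 1.06 (Hspa1a 4.56), unfolded protein response genes 0.92 (Hspa5 2.39), immediate early genes 0.67 (Egr2 3.72) and glucocorticoid-induced genes 0.97 (Cdkn1a 4.02). For heat shock and unfolded protein response genes, a part from tract tissue on the GW4869 overload array cannot be told apart. Genes induced by cAMP had 0.76, with Nr4a3 at 9.40 against a vehicle reading within background. Ribosomal protein genes had 0.56 (Rplp0 1.00), vesicle biogenesis genes 0.37 (Cd9 2.75) and B cell markers 0.84 (0.29 over all 17 measured; Cd79a at least 2.21). Sperm genes had 1.00, or 0.00 with values under the floor set to it, and smooth muscle markers 0.49 (Actg2 at least 6.85). In total 2156 genes were higher and 2202 lower, 25 of 35 lists stood apart, and the median gene differed by -0.04. Centred on adipocyte genes, oxidation genes had -0.33, oxidative phosphorylation genes -0.13, mature adipocyte genes -0.30, glucose handling genes -0.06 and endothelial markers -0.20, and the median gene 0.48. Fatty acid synthesis genes then had -1.04, triglyceride synthesis genes -0.49, thermogenic genes -0.23 and mast cell markers -0.21. The share of higher genes was 49.5%, against 30.1% with all-gene centring and 89.9% when centred on adipocyte genes.

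The overload differences under vehicle and under GW4869 did not run in parallel. Their correlation across genes was r = -0.14 (Spearman's rho -0.13), with no array in common, and -0.09 without the 606 genes that spanned 4 log2 units or more. The arrays with sperm or proximal epididymis transcripts, vehicle sham and GW4869 overload, lie on opposite sides of the 2 comparisons. Tract RNA therefore cannot be told apart from an altered overload response, here or in the counts below. Genes higher with overload in both numbered 361, where 473 would be shared by independent sets, and genes lower in both 291, where 301 would be. Genes higher under vehicle and lower under GW4869 numbered 647 (540 for independent sets), and the opposite kind 491 (264). These counts depend on the scaling. With all-gene centring, after trend removal and centred on adipocyte genes, the first kind numbered 1473, 319 and 127 (1344, 240 and 101 for independent sets) and the opposite kind 339, 637 and 1210 (141, 411 and 958). Genes higher in both then numbered 538, 231 and 592 (720, 265 and 719), and genes lower in both 246, 382 and 181 (264, 372 and 135). The difference between the overload differences was at least 1.5-fold positive for 2519 genes and negative for 4252. The highest were the tract genes Adam7, Cuzd1, Lcn5, Wfdc10, Lcn12, Eppin and Ptgds, high on the vehicle sham and GW4869 overload arrays with levels of 8.85 to 18.09, and Prm2, at 17.92 and 6.74. The lowest were Pon1 (-5.25 or lower), Cyp2f2 (-4.88), Angpt1 (-4.28), Tecpr1 (-3.77 or lower), Bnc2 (-3.83), C6 (-3.82) and the major urinary protein family, whose members had -4.52 or lower and -3.35 or lower.

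By list, this difference was 12.35 for sperm genes and 11.41 for epididymal genes, or 9.74 and 9.35 with values under the floor set to it. It was 2.09 for inflammatory genes, 2.06 for heat shock genes and 1.22 for the unfolded protein response (1.51, 1.48 and 0.64 with all-gene centring). It was -1.85 for fatty acid synthesis, -1.30 for fatty acid oxidation, -1.27 for fibroblast markers, -1.07 for matrix genes, -0.91 for mature adipocyte genes and -0.88 for glucose handling. These 11 were among the 19 of 35 lists that stood apart. Lipolysis genes had -0.62, within the random range, with 13 of 24 lower and 1 higher, and 0.09 when centred on adipocyte genes. Centred on adipocyte genes, synthesis had -1.15, oxidation -0.60, fibroblast markers -0.57, matrix genes -0.37, mature adipocyte genes -0.20 and glucose handling -0.18. The share of positive genes was 37.2%, against 18.5% with all-gene centring, 57.5% after trend removal and 76.9% when centred on adipocyte genes. Each of these values rests on all 4 arrays, of which vehicle sham, GW4869 overload and, for distal genes, GW4869 sham carried tract transcripts.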

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

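All tests of explanations in this part were chosen after the result was seen. Each list below differed in direction between the vehicle and GW4869 mice, or between sham and overloaded mice, and none of these differences was tested, since each group has 1 array. Fatty acid oxidation genes had median log2 differences with overload of 0.84 under vehicle and -0.40 under GW4869, thermogenic genes 0.88 and -0.61, insulin and glucose handling genes 0.67 and -0.40, and endothelial markers 0.78 and -0.57. The oxidation and glucose values under GW4869 turned to 0.04 when arrays were centred on adipocyte genes. Heat shock genes had -0.56 (-0.09 with all-gene centring and -0.23 after quantile normalization) and 1.25. Tfap2a had -1.05 (-0.58 with all-gene centring and -0.67 with values under the floor set to it) and 1.05. The thermogenic value under vehicle was 0.47 with values under the floor set to it and 0.08 over all 14 measured members, both within the random range. Unfolded protein response genes had -0.44 and 0.49 with overload, and with GW4869 -0.12 in sham and 0.92 in overloaded mice. The first turned to 0.03 and the third to 0.25 with all-gene centring. Vehicle sham and GW4869 overload, the arrays with sperm or proximal epididymis transcripts, lie on opposite sides of the overload comparisons. Oxidation genes were lowest there (11.43 and 11.18 against 12.43 and 11.84), as were endothelial markers. Heat shock genes were highest there (10.07 and 10.73 against 9.46 and 9.68), as were unfolded protein response genes. A part from tract tissue in these changes of direction cannot be told apart. Epididymal genes had -0.59 and 9.21 with overload, and -0.51 and 9.79 with GW4869 in sham and overloaded mice. Sperm and testis genes had -10.74 and 1.52, and -11.08 and 1.00. With values under the floor set to it, the epididymal -0.59 and -0.51 became 0.00 and -0.08 and the sperm 1.52 and 1.00 became 0.00 and 0.00, so these rest on readings at background. Outside the named genes, 325 unnamed probe sets of 1338 above the floor were at least 1.5-fold higher in vehicle overload than in vehicle sham, and 327 were lower.

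Sperm and testis genes were high on the vehicle sham array alone, at a median of log2 14.04. The median difference was -10.70 after quantile normalization. The arrays were already alike before that step, with medians of 5.62 to 6.09. It could therefore not have removed a difference of this size, and it does not decide on a normalization effect. A sham-wide difference is argued against by the GW4869 sham array, whose sperm genes lay -0.38 from vehicle overload. A reproductive organ in place of fat is argued against by adipocyte genes, 0.38 apart between the 2 vehicle arrays. RNA from testis or epididymis in the dissected fat may explain the pattern, and no biological explanation was tested. Of 20 epididymal genes, only 6 were also at least 4 log2 units above vehicle overload. Leydig cell genes, listed after seeing the data, had a median of 7.74 on this array against 3.80 on vehicle overload, although Star was at 3.37, under the floor. Sertoli cell genes had a median of 3.67, under the floor, although Inha was at 8.33.

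Fatty acid synthesis genes were low on the GW4869 overload array, with a median of -1.38 against GW4869 sham. Dilution of adipocyte RNA by other tissue is argued against as the whole cause, because mature adipocyte genes had a median of -0.40 and a 10th percentile of -0.88, and 10 of 15 synthesis genes lay below the latter. The median was -1.27 after quantile normalization, but the 2 GW4869 arrays were already alike, with medians of 5.73 and 5.84. That step could not have removed a difference of this size and does not decide on a normalization effect. Trend removal left -1.25, which argues only against an intensity trend shared by genes of like brightness. An effect of overload under GW4869 may remain, but it rests on 1 mouse or pool per group, and feeding state and other differences between animals stay open.

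Dbp and Per3, clock output genes chosen after their values were seen, were higher in overload than in sham under both injections, by 1.99 and 1.71 under vehicle and 2.27 and 0.66 under GW4869. The clock list fixed before the data were examined had medians of 0.82 and 0.15, the latter within the random range, and Per1 had -0.33 under GW4869. Whether reproductive-tract RNA in 1 array gives the pattern cannot be told, because the output arm, which stood at least 0.69 above the median gene, was assembled after its values were seen and holds Tef and Hlf, under the floor. Distal tract RNA in both sham arrays could lower clock genes there only by dilution, which is argued against under GW4869 by mature adipocyte genes, at -0.40 with overload, but stays open under vehicle, where they had 0.38. Arrays taken at different times of day could also give it, and the opposite-phase arm leaves this open, with a higher median of -0.17 relative to the median gene over 5 genes.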

How the results depend on the processing

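Setting values under the floor to it, centring on adipocyte genes, centring on genes above the floor, dropping tract genes or genes spanning 4 log2 units, and the Veh-SA against GW-Sham comparison were chosen after seeing the data. No paired analysis was possible because each group has 1 array. For overload under vehicle, overload under GW4869, GW4869 in sham, GW4869 in overload and the difference of the overload differences, genes at least 1.5-fold apart numbered 8570, 5227, 7708, 6725 and 10777 with no floor, 3426, 1969, 3073, 2758 and 4294 with a floor at the 60th percentile, and 2784, 1351, 2581, 1866 and 4247 at a 2-fold threshold, since these settings count more or fewer genes by construction. Vehicle overload against GW4869 sham gave 3044 in place of 5509. The overlap of the overload comparisons, 652, was 1016, 332 and 206 under the same 3 settings. Lipolysis under vehicle was 0.40 as a mean over members (percentile 97.6). Tfap2a with GW4869 in sham was 0.94 with all-gene centring and 0.95 after quantile normalization, and -0.58 with overload under vehicle with all-gene centring. With all-gene centring the direction reversed for cholesterol synthesis (overload under vehicle 0.24, GW4869 in sham 0.11), cell cycle (GW4869 in sham 0.072), unfolded protein response (0.032 and 0.25 in the same 2 comparisons), mesothelial markers (overload under vehicle 0.29) and ribosomal proteins (difference of differences -0.30). It also reversed for oxidative phosphorylation with GW4869 in sham (-0.15 after trend removal and -0.15 centred on adipocyte genes), cholesterol synthesis there with the 60th-percentile floor (0.023), and, centred on adipocyte genes, fatty acid oxidation and insulin and glucose handling with overload under GW4869 (0.038 and 0.038) and clock genes with GW4869 in overload (0.10). Mesothelial markers in the difference of differences had 0.23 as a mean. Where no construction is named, the cause was not tested. The 3 centrings add a constant to a comparison and to its random lists, so they cannot move a percentile, and 11 of the 14 reversals come from them by construction. Of 1530 list values under the other settings, 1415 stayed on their side of the random range, though some of them took the opposite sign (inflammatory genes with overload under vehicle, 0.32, had -0.83 as a mean), 52 moved out of it, 60 moved into it and 3 reversed. The median gene for overload under vehicle, 0.26, was 0.73 with all-gene centring, -0.04 after trend removal and -0.01 centred on adipocyte genes. Centred on adipocyte genes it went from -0.04 to 0.40 for overload under GW4869, from -0.04 to 0.48 for GW4869 in overload and from -0.27 to 0.44 for the difference of differences. The correlation between overload differences lay between -0.09 and -0.17 under the alternatives other than centring, which cannot move it. Signal over background limits all of this, as negative control medians reached 5.20, above the floor of 4.67, and their 95th percentiles lay between 9.01 and 9.27, with 6.34 to 6.40 for antigenomic background probes.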

Other observations

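Tests of explanations were chosen after the result was seen, and this part adds none. Vehicle overload against GW4869 sham leaves out the arrays with sperm or proximal epididymis transcripts, but GW4869 sham holds distal tract transcripts at a median of 12.87 against 3.19, and both factors differ. It gave 1299 genes at least 1.5-fold higher in vehicle overload and 1745 lower. Leydig cell genes, from a list made after seeing the data, were high on the vehicle sham array, with a median of log2 7.74 against 3.80, 3.48 and 3.03 on vehicle overload, GW4869 sham and GW4869 overload. Cyp17a1, a steroid-making enzyme, was at 14.49, Hsd3b6 at 12.87 and Hsd3b1 at 9.39 there. Cyp11a1 and Hsd17b3, at 6.10 and 5.96, lay below the 95th percentile of antigenomic background probes (6.40), and Star, at 3.37, under the floor. Spermatid genes had a median of 14.65 on that array, spermatocyte genes 8.37 and Sertoli cell genes 3.67, under the floor, although Inha of the last was at 8.33. Proximal epididymis genes had a median of 14.19 on the GW4869 overload array against 3.80 or less on the others. Seminal vesicle genes had 9.39 there, with Svs2 at 15.17 and Svs5 at 14.32, against list medians of 5.42, 4.32 and 5.52 on vehicle sham, vehicle overload and GW4869 sham.

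T cell markers, with 4 members above the floor and so no random range, had medians of 1.03 with overload under vehicle and 1.03 with GW4869 in sham. They had -0.18 and -0.26 in the other comparisons. Both 1.03 values subtract the vehicle sham array, where these members had a median of 4.92. Their medians were 5.98, 5.82 and 5.64 on vehicle overload, GW4869 sham and GW4869 overload. Plasma cell markers (4 members) had 0.48, 0.31, 1.06 and 0.89 for overload under vehicle, overload under GW4869, GW4869 in sham and GW4869 in overload. Klrb1c, the 1 natural killer cell marker above the floor, had 0.21, 2.44, 0.00 and 2.22 in that order with values under the floor set to it. Schwann cell and nerve markers (3 members) had 0.29, 0.34, 0.60 and 0.66, with Mal at -3.96, 3.06, -0.68 and 6.33. Erythroid markers (2 members) had 0.28, 0.19, 0.63 and 0.54. Clock genes with GW4869 in overload had -0.43, with 5 of 14 higher and 5 lower, or 0.10 centred on adipocyte genes. Genes spanning 4 log2 units or more over the 4 arrays numbered 606.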
